A study of Saccharomyces cerevisiae with 48 samples.

How the data were processed

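Total DNA was sequenced from synchronized meiotic cultures of budding yeast (Saccharomyces cerevisiae) sporulating in 2% potassium acetate at 30 °C, per the labels' protocols. The labels name 6 strains sampled at 8 times each, from 0 to 4 hr, which makes 48 samples. The strains combine 3 backgrounds (wild type, DDK OP and tof1∆) with 2 states of chromosome III (ARS+ and ars∆). DDK is the Cdc7-Dbf4 kinase that activates replication origins and is overproduced in the strains called DDK OP. Tof1 is a component of the replication fork that holds the kinase there. An ARS is a replication origin. The study is known to have removed active origins from the left arm of chromosome III in the ars∆ strains.

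The authors deposited 1 table per strain, and the values are ratios. Reads were aligned with BWA to sacCer2, per the submitters' processing notes, and the version of BWA is not given in the sources used here. Each table lists the same 4568 positions on 16 chromosomes, 2.5 kb apart, with 41 gaps in which 101 positions are not listed. The 7 columns of a table are the times from 1 to 4 hr, so 42 samples have values and the 6 samples at 0 hr have no column. The ratios run from 0.549 to 1.47, and the mean per sample lies between 1.0003 and 1.0023. What they were divided by is not stated. The correlation over positions of a 1 hr sample with later samples of its own strain was 0.49 at the median, against 0.083 with samples of other strains. Division by the strain's own 0 hr sample would give such a pattern, and this denominator is inferred here, not recorded. Neighbouring positions correlated at 0.53 and positions 2 steps apart at 0.15 (medians of the 1 hr samples), as overlapping windows would. No counts are in the tables, so the depth is unknown and no counting interval is given.

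The 8 samples of a strain are one culture, so the unit of replication was the culture, with 6 in all and 1 per strain. The replication index of a culture was the mean over 1 to 4 hr of log2 of the ratio divided by the median ratio of that sample, averaged over the positions of each 10-kb window. This gave 1174 windows, of which 1097 hold all 4 positions and 77 fewer. A higher index means more copies relative to the rest of the genome, as in DNA replicated earlier. Windows were compared with limma (version 3.58.1, R 4.3.3; lmFit and eBayes) on the 6 indices, with terms for background and ars deletion, 2 residual degrees of freedom and a prior of 29.8 degrees of freedom. Adjusted p-values are Benjamini-Hochberg over all windows, with a threshold of 0.05. ARS+ and ars∆ cultures of a background served as its replicates for the DDK and tof1 comparisons, so these p-values rest on the spread between 6 cultures only. Ratios called for limma, and the count model written for the case of read counts was not used. The subtraction of 0 hr values and the exclusion of positions with unusual 0 hr coverage, both planned, were not run because the 0 hr values are not listed.

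A second index was added after the data were examined: the mean of 2 to 4 hr minus the value at 1 hr of the same culture, in which any shared denominator cancels. A further one used 2.5 to 3.5 hr minus the mean of 1 and 1.5 hr. The left region of chromosome III was the first 100 kb, its right part began at 150 kb, and both bounds were set before the data were examined. The shift of the left region was tested over the 3 pairs by an exact two-sided sign-flip permutation, whose smallest p is 0.25. Lists of windows were compared with all other windows by the same exact test over 6 cultures, whose smallest p is 0.031, with Benjamini-Hochberg adjustment over 6 lists. DDK and tof1 against wild type is 2 cultures against 2 for any single value, where an exact test cannot go below 0.333, so values alone are given. The lists were windows within 10 kb of a centromere, the outer 30 kb of each chromosome, 8 early and 4 late origins of mitotic cells placed by rounded position, the right part of chromosome III, and the small chromosomes I, III, VI and IX. A subset of 5 early origins was added afterwards. It leaves out ARS305 and ARS306 in the left region, and ARS307 just beyond it, at 100001 to 110000.

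The time course of each culture was described by the SD over windows in each sample, and by the slope of each sample on a shared replication programme. The programme was the second index averaged over the 4 cultures of the other backgrounds, with chromosome III left out. Subtraction of 1 hr values in the programme favours slopes at or below 0 at 1 hr. Intervals of 95% came from 1000 bootstrap draws of the 15 chromosomes and leave out the spread between cultures.

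The named windows were, for each comparison, the 10 largest increases and decreases among called windows, all of them where fewer passed, and the 3 with the lowest p where none did. No annotation of the sacCer2 build was used here, so no genes are named, and the altered genes and deleted origins were not checked in the data. The ribosomal DNA, at 450 to 490 kb of chromosome XII, has 3 listed positions and was not analysed as a list. The fit was tested on simulated data, with a single SD for all windows, pooled from the residuals of the real ones. For each comparison 50 windows were changed at each of 0.05, 0.10, 0.15 and 0.20, far more than were called in the data. So many changes make adjusted p-values easier to pass, so the simulated counts can overstate the power in the real data. Of 50 windows changed by 0.10 on the log2 scale, 35 were called for ars deletion, 16 for DDK and 26 for tof1. At a change of 0.20 the calls were 50, 49 and 49 of 50. Among 974 unchanged windows, 1, 6 and 1 were called. The alternatives were other window sizes, scaling by the mean, a trend in eBayes, 1.5 to 3 hr alone, one SD for all cultures, other bounds of the left region, and cultures or pairs left out. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.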

Results

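Replication in meiotic S phase was followed as relative copy number along 16 chromosomes in 6 cultures, at 7 times from 1 to 4 hr after transfer to sporulation medium. The cultures were ARS+ and ars∆ derivatives of wild type, DDK OP and tof1∆, 1 culture each. Values are differences on the log2 scale relative to the median position of the sample, in sacCer2 coordinates. A region rises when it replicates before most of the genome and returns towards 0 as the rest catches up. The sequencing depth is unknown.

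The slope on the shared replication programme rose after 1 hr and was highest at 3 or 3.5 hr in these cultures. The programme subtracts 1 hr values, so a slope near 0 at 1 hr cannot show that replication had not begun. At 1 hr the slope on the programme shared by the other backgrounds lay between -0.096 and 0.00065. It was highest at 3.5 hr in wild-type ARS+ (0.98, 95% bootstrap interval 0.87 to 1.06) and at 3 hr in wild-type ars∆ (1.28, interval 1.15 to 1.38). In both tof1∆ cultures it was highest at 3 hr, with 1.26 (interval 1.17 to 1.33) in ARS+ and 1.21 (interval 1.06 to 1.34) in ars∆. The DDK OP cultures had their highest slopes, 0.84 (interval 0.76 to 0.93) at 3 hr in ARS+ and 0.83 (interval 0.72 to 0.94) at 3.5 hr in ars∆. At 1.5 hr the DDK OP ars∆ culture alone had an interval above 0, with a slope of 0.27 (interval 0.18 to 0.38). The SD over 10-kb windows peaked at the same times in each culture, at 0.081 ± 0.0094 (SD, n = 6 cultures) on average. Each background has 2 cultures, which also differ in ars state, and differences in timing between backgrounds were not tested.

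**Figure D1:**
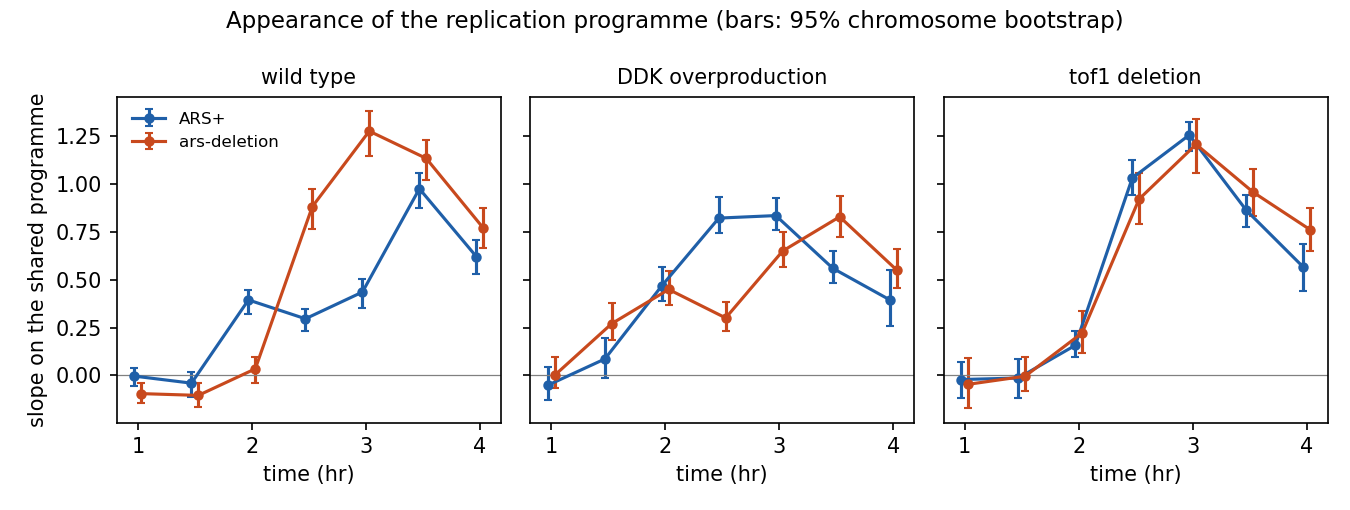
Slope of each sample on the replication programme shared by the other backgrounds, against time in hours, for ARS+ (blue) and ars∆ (orange) cultures of the 3 backgrounds. Bars are 95% intervals from resampling chromosomes; slopes at 1 hr lie between -0.096 and 0.00065, and the highest is 1.28 in wild-type ars∆ at 3 hr.

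Windows near centromeres replicated early in all 6 cultures. The 48 centromeric windows exceeded the other windows by 0.060 ± 0.0097 (SD, n = 6, exact sign-flip p = 0.031, adjusted p = 0.038; higher in 6 of 6 cultures). Their excess was 0.013 ± 0.0044 (SD, n = 6) at 1 hr, reached 0.10 ± 0.027 (SD, n = 6) at 3 hr and was 0.062 ± 0.010 (SD, n = 6) at 4 hr. The 87 windows at chromosome ends differed from the rest by -0.0066 ± 0.016 (SD, n = 6, exact p = 0.31, adjusted p = 0.31; lower in 3 of 6 cultures). With the value at 1 hr subtracted, centromeric windows exceeded the rest by 0.064 ± 0.010 (SD, n = 6, exact p = 0.031, adjusted p = 0.094 over the 6 lists; higher in 6 of 6 cultures).

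The windows of the 8 early origins exceeded the others by 0.086 ± 0.026 (SD, n = 6, exact p = 0.031, adjusted p = 0.038; higher in 6 of 6 cultures). ARS606 on chromosome VI (160001 to 170000) had a mean index of 0.18 ± 0.037 (SD, n = 6), and ARS607 (190001 to 200000) one of 0.14 ± 0.033 (SD, n = 6). ARS416 on chromosome IV, the first yeast origin isolated, had 0.063 ± 0.044 (SD, n = 6). With the value at 1 hr subtracted these were 0.075 ± 0.030, 0.074 ± 0.037 and 0.080 ± 0.054 (SD, n = 6). The 4 late origins exceeded the other windows by 0.042 ± 0.029 (SD, n = 6, exact p = 0.031, adjusted p = 0.038; higher in 6 of 6 cultures). Of the early origins 7 of 8, and of the late ones 3 of 4, lie on chromosomes III and VI, whose means at 1 hr were 0.065 and 0.094. The late origin elsewhere, ARS522 on chromosome V, had -0.022 ± 0.021 (SD, n = 6). The excess of the early origins was already 0.074 ± 0.030 (SD, n = 6) at 1 hr. With that value subtracted it was 0.018 ± 0.029 (SD, n = 6, exact p = 0.22, adjusted p = 0.26; higher in 4 of 6 cultures) and no longer passed. This test pools both states of chromosome III. The excess was 0.049, 0.038 and 0.038 in the ARS+ cultures of wild type, DDK OP and tof1∆. In their ars∆ cultures it was 0.014, -0.016 and -0.018. On the same index, the late origins were below the other windows, by -0.031 ± 0.018 (SD, n = 6, exact p = 0.031, adjusted p = 0.094; lower in 6 of 6 cultures). The 5 early origins other than ARS305, ARS306 and ARS307 were higher on that index, by 0.052 ± 0.016 (SD, n = 6, exact p = 0.031; higher in 6 of 6 cultures). ARS307, which lies just beyond the left region of chromosome III, had -0.0031 ± 0.060 (SD, n = 6). That mean joins 0.046 ± 0.021 (SD, n = 3) in ARS+ with -0.052 ± 0.036 (SD, n = 3) in ars∆. None of the 12 origin windows passed limma for DDK or tof1 on either index. At an unadjusted p under 0.05, 2 did for DDK and 0 for tof1 on the index of 1 to 4 hr, and 3 and 2 with the value at 1 hr subtracted.

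Windows on chromosomes I, III, VI and IX exceeded the rest by 0.058 ± 0.018 (SD, n = 6, exact p = 0.031, adjusted p = 0.038; higher in 6 of 6 cultures), and the excess was already 0.056 ± 0.025 (SD, n = 6) at 1 hr. At 4 hr it was 0.036 ± 0.029 (SD, n = 6), with tof1∆ ARS+ at -0.0096. Chromosomes I, III and VI had mean values of 0.11, 0.065 and 0.094 at 1 hr, whereas chromosome IX had -0.0082. The right part of chromosome III exceeded the rest by 0.045 ± 0.023 (SD, n = 6, exact p = 0.031, adjusted p = 0.038; higher in 6 of 6 cultures). With the value at 1 hr subtracted, the small chromosomes differed by 0.0021 ± 0.016 (SD, n = 6, exact p = 0.75; higher in 3 of 6 cultures) and the right part of III by -0.020 ± 0.019 (SD, n = 6, exact p = 0.063; lower in 5 of 6 cultures).

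Removal of origins on chromosome III asks how far replication of the left arm depends on them. Over the first 100 kb of chromosome III (36 positions), the index was lower in ars∆ than in ARS+ in all 3 backgrounds. The difference was -0.092 in wild type, -0.12 in DDK OP and -0.040 in tof1∆, with a mean of -0.083 ± 0.039 (SD, n = 3 pairs, exact sign-flip p = 0.25, the smallest possible). Among 118 other 100-kb regions the lowest mean difference was -0.026, so none was as low. For tof1∆ alone, 3 other regions were as low. The right part of chromosome III (62 positions) differed by 0.025 ± 0.042 (SD, n = 3 pairs, exact p = 0.50; lower in 1 of 3 pairs), and the other 15 chromosomes by 0.0012 ± 0.00038 (SD, n = 3 pairs). Those 15 hold 4450 of the 4568 positions, so division by the sample median keeps their mean near 0 in every culture.

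The difference in the left region developed during S phase. At 1 hr it was 0.017 ± 0.054 (SD, n = 3 pairs) and at 2 hr -0.026 ± 0.10 (SD, n = 3 pairs). It reached -0.17 ± 0.012 (SD, n = 3 pairs) at 3 hr and -0.18 ± 0.074 (SD, n = 3 pairs) at 3.5 hr, and was -0.15 ± 0.054 (SD, n = 3 pairs) at 4 hr. The wild-type ars∆ culture went from 0.097 at 2 hr to -0.15 at 3.5 hr, while wild-type ARS+ stood at 0.069 and 0.11. With the value at 1 hr subtracted the difference was -0.16 in wild type, -0.11 in DDK OP and -0.15 in tof1∆, with a mean of -0.14 ± 0.026 (SD, n = 3 pairs, exact p = 0.25). On that index none of the 118 other regions was as low in any of the 3 pairs. The difference between backgrounds was not tested, since each has 1 pair.

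**Figure D2:**
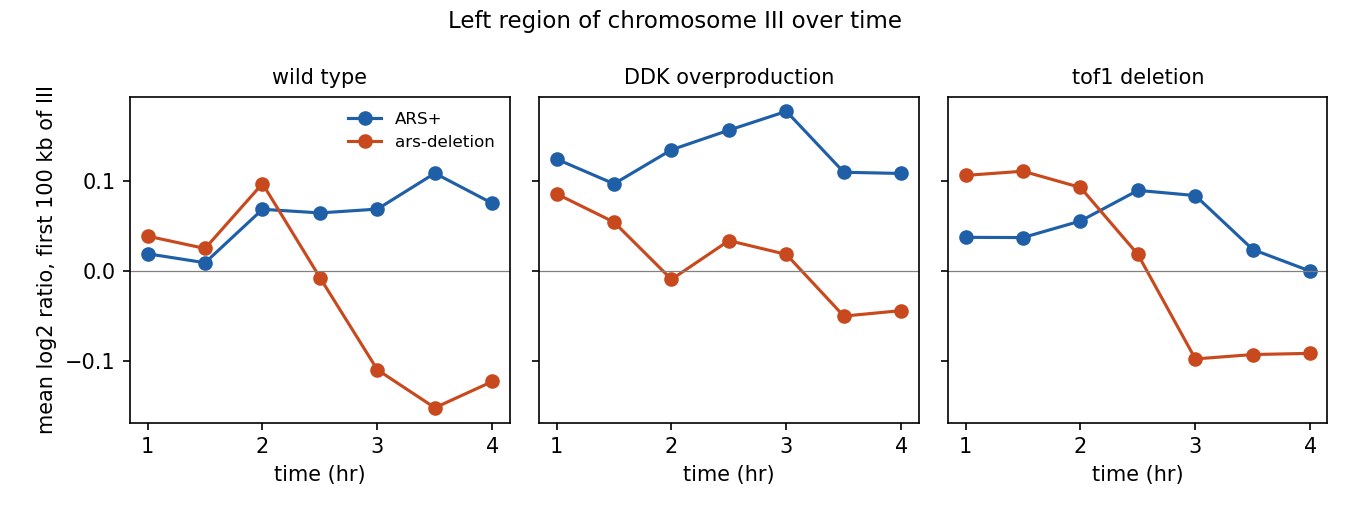
Mean log2 ratio over the first 100 kb of chromosome III against time in hours, for the ARS+ (blue) and ars∆ (orange) culture of each background; each point is 1 sample. The mean difference between ars∆ and ARS+ is 0.017 at 1 hr and -0.17 at 3 hr.

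Window by window, the clearest change with ars deletion was a continuous block of the left arm. With the value at 1 hr subtracted, limma called 6 of 1174 windows, all lower in ars∆ and all adjacent, from 30001 to 90000 on chromosome III. The largest difference was at 80001 to 90000, -0.20 (SE 0.030, adjusted p = 0.0037), where 2 positions are listed. The window of ARS305 (30001 to 40000) differed by -0.17 (SE 0.025, adjusted p = 0.0037), with 0.050 ± 0.046 (SD, n = 3) in ARS+ and -0.12 ± 0.075 (SD, n = 3) in ars∆. The window of ARS306 (70001 to 80000) differed by -0.16 (SE 0.027, adjusted p = 0.012). ARS307 (100001 to 110000) differed by -0.098 (SE 0.025, adjusted p = 0.16) and did not pass, nor did ARS310 on the right arm, at -0.020 (SE 0.027, adjusted p = 0.998). All 3 pairs were lower over a run of 10 windows from 20001 to 120000. Elsewhere 10.4% of windows were lower in all 3 pairs, where chance gives 12.5%. Without the wild-type pair limma called no window, with 57 at an unadjusted p under 0.05, and without the DDK OP pair it called 13. Of these 13, 7 lie in the left region and 5 off chromosome III. Without the tof1∆ pair it called 9, with 6 in the left region and 3 off chromosome III. The calls were thus confined to the left arm only with all pairs in the fit.

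On the index of 1 to 4 hr, which was fixed before the data were examined, limma called 2 windows for ars deletion. The window at 80001 to 90000 on chromosome III, with 2 listed positions, was lower in ars∆ by -0.23 (SE 0.029, adjusted p = 6.9e-06). At 1 hr its difference was already -0.069, or 0.30 of the full one, with -0.21 in wild-type ars∆ and -0.019 in wild-type ARS+. The other, at 260001 to 270000 on chromosome II, was higher by 0.15 (SE 0.029, adjusted p = 0.0055). Its difference was -0.026 (adjusted p = 0.998) with the value at 1 hr subtracted, and it did not pass in 5-kb windows (adjusted p = 0.16). ARS305 and ARS306 differed by -0.11 each (SE 0.028, adjusted p = 0.089). Adjusted over the list alone, 7 of the 10 windows of the left region and 2 of the 8 early origin windows passed, against 1 and 0 over all windows. In the same way 4 of the 10 left-region windows passed for DDK and 3 for tof1, and no early origin window did. The limma count for ars deletion over all windows was 0 without the wild-type pair, with 47 windows at an unadjusted p under 0.05, and 9 without the DDK OP pair.

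**Figure D3:**
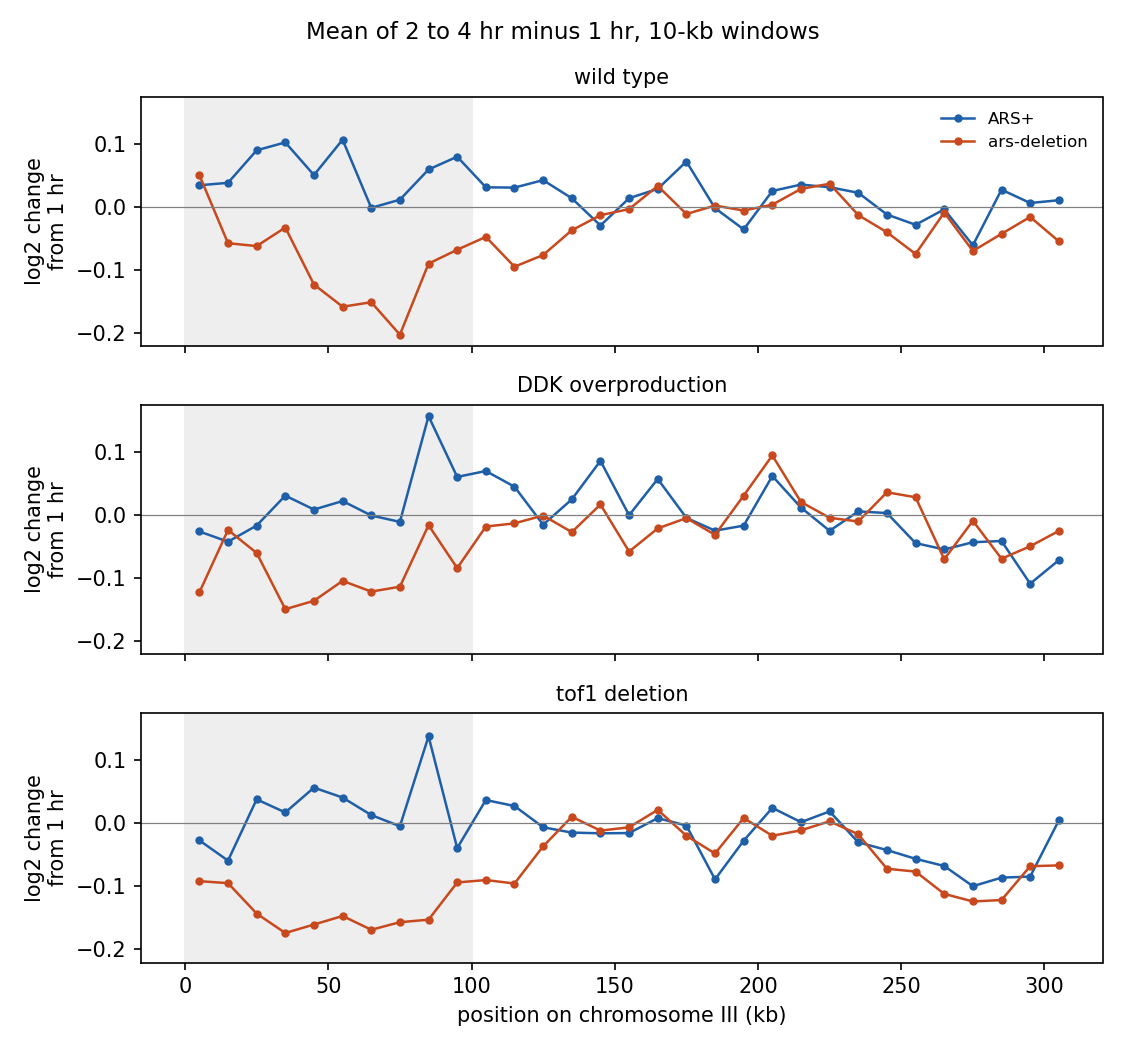
Mean of 2 to 4 hr minus 1 hr (log2) in 10-kb windows along chromosome III, in kb, for the ARS+ (blue) and ars∆ (orange) culture of each background; the grey band is the first 100 kb. The ars∆ line is lower in all 3 backgrounds from 20 to 120 kb.

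Overproduction of DDK left nearly all windows without a detectable difference from wild type. On chromosomes other than III limma called 1 window, at 1090001 to 1100000 on chromosome IV, and on III none. It was at 0.12 in DDK OP and -0.17 in wild type (means of 2 cultures), a difference of 0.28 (SE 0.038, adjusted p = 1.8e-05), and with the value at 1 hr subtracted the difference was 0.24 (SE 0.042, adjusted p = 0.038). Centromeric windows differed from wild type by 0.015 in ARS+ and -0.024 in ars∆, and early origins by 0.068 and 0.0051. The rise in ARS+ was not particular to early origins. Late origins differed by 0.061 and -0.012, and small chromosomes by 0.040 and -0.00042. The right part of III differed by 0.046 and -0.016, and chromosome ends by -0.035 and 0.010. At 1 hr the early origins already differed by 0.079 and 0.028, and with these values subtracted the differences turned to -0.011 and -0.030. Without the wild-type ARS+ culture limma called no window, with 56 at an unadjusted p under 0.05, and without the DDK OP ARS+ culture it called 11 off chromosome III. A further window, at 10001 to 20000 on chromosome X, passed when the value at 1 hr was subtracted (0.26, SE 0.032, adjusted p = 0.0016), with 1 position listed.

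For deletion of TOF1 limma likewise called few windows. Smaller changes can be missed, since 26 of 50 simulated windows changed by 0.10 were called, and the simulation can overstate the power. On chromosomes other than III limma called 3 windows, all lower than in wild type. They were at 480001 to 490000 on chromosome XII, in the stretch assigned to the ribosomal DNA (-0.26, SE 0.045, adjusted p = 0.00093), at 10001 to 20000 on chromosome IV (-0.24, SE 0.037, adjusted p = 0.00019), and at 180001 to 190000 on chromosome I (-0.16, SE 0.034, adjusted p = 0.012). The first rests on 1 listed position and the second on 2. On chromosome III the window at 80001 to 90000, with 2 listed positions, was higher by 0.23 (SE 0.036, adjusted p = 0.00019). At 1 hr tof1∆ already stood there at 0.077 in ARS+ and 0.10 in ars∆, against -0.019 and -0.21 in wild type. With the value at 1 hr subtracted, limma gave that window a difference of 0.0081 (adjusted p = 0.98). Limma called no window with the value at 1 hr subtracted, where 95 had an unadjusted p under 0.05 and the windows on XII and IV turned to 0.067 and 0.080. It called none in 5-kb windows, where 112 had an unadjusted p under 0.05. Limma called none without the wild-type ars∆ culture or without the tof1∆ ars∆ culture, with 50 and 77 at an unadjusted p under 0.05, and 6 off chromosome III without either DDK OP culture. Centromeric windows differed from wild type by 0.014 in ARS+ and -0.014 in ars∆, and early origins by 0.012 and 0.014. With the value at 1 hr subtracted, the differences at early origins turned to -0.012 and -0.033. On that index 89 of the 119 small-chromosome windows and 65 of the 87 end windows were lower than in wild type. Of the 48 centromeric windows 24 were lower. For DDK OP these counts were 79, 64 and 31. Both sets of counts use the same 2 wild-type cultures. At the ends the difference was -0.056 in ARS+ and -0.010 in ars∆ for tof1∆, and -0.068 and 0.0097 for DDK OP. Wild-type ARS+ was the only culture with ends above the rest on that index, by 0.018. The share of lower windows over the whole genome was not counted. Such shifts of whole lists between backgrounds were not tested.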

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

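The coverage exclusion was not run, for lack of 0 hr values, and the count models did not apply. The indices that subtract early times, and the restriction to windows with all 4 positions, were chosen after seeing the data. The left-region shift of -0.083 stayed negative under every alternative run, from -0.066 to -0.10 with a pair left out, and was -0.14 for 2 to 4 hr minus 1 hr and -0.16 for 2.5 to 3.5 hr minus 1 and 1.5 hr. The ars-deletion count of 2 became 4 with a trend in eBayes, 6 for 2 to 4 hr minus 1 hr and 11 for 2.5 to 3.5 hr minus 1 and 1.5 hr, and ran from 0 to 9 with a pair left out. The count of 6 with the 1 hr value subtracted became 10 in 5-kb windows and ran from 0 to 13 with a pair left out. The DDK count of 1 became 3 for 1.5 to 3 hr and 2 with either early baseline subtracted, and ran from 0 to 11 with a culture left out. The tof1 count of 3 became 0 in 5-kb windows and 0 with either early baseline subtracted, and ran from 0 to 6 with a culture left out. The mean peak SD of 0.081 became 0.11 as an interquartile range, which is a wider measure by construction.

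With the 1 hr value subtracted, 3 called windows changed sign: that on chromosome II to -0.026, that on XII to 0.067 and that at the left end of IV to 0.080. Late origins went to -0.031 and the right part of III to -0.020. Leaving out a culture leaves its background with 1 culture, assumed to vary like the rest. Beyond the construction of the early baselines, the cause was not tested.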

Other observations

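All tests of explanations in this part, and the indices with early times subtracted, were chosen after the result was seen. The tests of a timing change, of replication under way at 1 hr and of forks from the right replaced earlier tests. The earlier ones had argued against these 3 explanations, and the present ones leave them open.

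At 4 hr the chromosome ends lay below the other windows by -0.037 ± 0.029 (SD, n = 6), from 0.015 ± 0.013 (SD, n = 6) at 1 hr, while centromeric windows were above by 0.062 ± 0.010 (SD, n = 6). The difference between ends and centromeres was not tested. With the 1 hr value subtracted, ends were lower in 5 of 6 cultures (-0.028 ± 0.024, SD, n = 6; exact sign-flip p = 0.063, adjusted p = 0.094), which did not pass.

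For ars deletion, 10 splits of the 6 cultures into 3 and 3 are too few for a share under 0.05. On the index of 1 to 4 hr the real split called 2 windows and the highest other 4, and 2 of the 10 splits called as many as the real one. With the 1 hr value subtracted the real split called 6 and the highest other 3, so 1 of the 10, the real one, called as many. Both splits that called 3 keep the 2 wild-type cultures together. With background as a block, their contrast is the DDK OP pair alone, which carries the ars deletion itself. The splits therefore cannot measure how many calls chance would give.

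The 5 windows called outside the left region of chromosome III on the index of 1 to 4 hr differed already at 1 hr, by 1.10 times the full difference at the median (range 0.33 to 1.26), so local copy number or the inferred 0 hr denominator may account for them. The lowest ratio, 0.33, belongs to the DDK window on chromosome IV, the one of the 5 that was also called with the 1 hr value subtracted. With that subtraction the difference was -0.17 of the full one at the median (range -0.34 to 0.84, opposite in sign in 3 windows). Only the DDK window kept most of it. In flanking windows, the earlier test, it was 0.19 of the full one at the median (range 0.023 to 0.27), and 0.12 for the DDK window. The 6 left-region windows called with the 1 hr value subtracted had a median flanking ratio of 0.96 on that index, and 0.94 on the index of 1 to 4 hr. They are adjacent, so most of their flanking windows are called windows themselves, and their ratio is no independent comparison. A timing change was thus not shown for these 5 windows, and stays open since the DDK window differed from the rest.

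The small chromosomes were already above the rest at 1 hr, by 0.056 ± 0.025 (SD, n = 6). The excess was 0.072 ± 0.017 (SD, n = 6) at 2.5 hr and 0.036 ± 0.029 (SD, n = 6) at 4 hr. At positions over 50 kb from both ends it was, at 1 hr, 0.049 ± 0.021 (SD, n = 6; higher in 6 of 6 cultures), which argues against nearness to ends. From 1 hr to its highest time it grew by 0.019 ± 0.015 (SD, n = 6), a measure that cannot fall below 0. In 5 of 6 cultures this was less than the excess at 1 hr, with no growth in tof1∆ ars∆, and only wild-type ARS+ grew by more. Replication already under way at 1 hr stays open. Differences in DNA recovery or library preparation between 0 hr and later samples also stay open, as the 0 hr values are not listed.

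In the ars∆ cultures, 10 to 40 kb of chromosome III exceeded 50 to 80 kb with the 1 hr value subtracted, by 0.12 in wild type, 0.036 in DDK OP and 0.020 in tof1∆, a mean of 0.059 ± 0.054 (SD, n = 3). In ARS+ the values were 0.038, -0.013 and -0.018. The order did not hold in every window, since 30001 to 40000 had -0.15 in DDK OP ars∆ and -0.17 in tof1∆ ars∆, below their values of -0.11 and -0.16 at 50 to 80 kb. Replication by forks from the right alone would leave the outer part later. A candidate explanation is that origins near the left end fire in some cells when the active ones are gone. The outcome depends on the use of the ARS+ partner. Alone, the ars∆ mean lies within 2 SD of 0. Less the ARS+ value of each background it was 0.082, 0.048 and 0.038, a mean of 0.056 ± 0.023 (SD, n = 3), beyond 2 SD. The mean hardly changed and the SD fell, as the ARS+ values lowered the wild-type difference and raised the other 2. Passive replication therefore stays open.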
